A study of Oryza sativa with 6 samples.

How the data were processed

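Small RNA of 15 to 30 nt was taken from gels, ligated to adaptors, amplified by 15 cycles of PCR and sequenced on an Illumina instrument, per the labels' protocols. The 6 libraries came from seedlings and 4-cm panicles of 93-11, osdcl4-1 and Nipponbare, with 1 library per group. The deposited tables hold, per the deposited note, each raw read with its count, identical reads being tallied by the authors with the 3-prime adaptor still in place. A second kind of deposited file, of the unit other, gives a string of base qualities for each read and was used for 5 libraries, all but Nipponbare seedlings. Tallying its reads gave the deposited count tables of these libraries exactly. The base caller and its version are not given in the sources used here. Reads were 35 nt long, and 33 nt in Nipponbare seedlings.

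The 3-prime adaptor was found by its first 8 bases with at most 1 mismatch, or by at least 5 bases at the end of a read, and inserts of 18 to 28 nt without undetermined bases were kept. Inserts holding a 10-nt stretch of either adaptor were left out. The trimming was tested on simulated data: it returned the right insert for 99.8% of inserts of 18 to 25 nt at both read lengths, and for 95.5% (33-nt reads) and 98.2% (35-nt reads) of inserts of 26 to 28 nt. Read counts were scaled to RPM over all kept inserts of 18 to 28 nt of a library. The limit that a count of 0 allows was taken as 3 counts per library, which is 1.05 RPM in 93-11 seedlings, 0.727 in 93-11 panicles, 1.30 in osdcl4-1 seedlings, 0.677 in osdcl4-1 panicles, 1.29 in Nipponbare seedlings and 0.953 in Nipponbare panicles.

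Shares of reads were given exact binomial (Clopper-Pearson) intervals, ratios of counts exact conditional binomial intervals and medians order-statistic intervals, all at 95%. Intervals of shares and medians over tags take each tag as a separate unit, although tags can be strands of the same duplex. Reads of 20 to 24 nt were assigned to 33 families by the sequence at their 5-prime end: 22 conserved miRNA families, 8 monocot families, 2 phasiRNA triggers (miR2118 and miR2275) and 1 TAS3 product (tasiR-ARF). A family counted as lower or higher when its RPM differed at least 2-fold, its interval excluded a ratio of 1 and the pair held at least 20 reads. The families named were, by a rule fixed in advance, the 8 largest falls and 8 largest rises past this rule and always miR162, miR168, miR390, miR2118, miR2275 and tasiR-ARF. The miRNA lists and roles came from general knowledge.

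Phased loci, genome windows and reads of organelles, tRNA and other rRNA were planned but not analysed here, because no genome was used. They were replaced, after the libraries had been seen, by tags: distinct inserts of 20 to 24 nt outside the 33 families, with no family sequence at any place in the insert. Tags needed at least 10 reads in a library outside the compared pair and 20 reads in the pair, and counted as lower or higher at 4-fold with an interval excluding 1. The choosing library was Nipponbare of the same tissue for osdcl4-1 against 93-11, both Nipponbare libraries added together for the tissues of 93-11 and osdcl4-1, both 93-11 libraries added together for the tissues of Nipponbare, and osdcl4-1 of the same tissue for the wild types. Log2 ratios used 0.5 added reads. In place of named loci, the 10 most abundant 21-nt sequences of 93-11 panicles were named. Duplex partners were sought among the reads of the same length at each overhang from -6 to 8 nt, after thinning every library to 2314501 inserts. Shares at other overhangs leave out 1 and 3 nt. Reads over tags were those of 20 to 24 nt sharing a 16-nt stretch with a tag on either strand, reads of the miRNA families included. The 5.8S rRNA sequence came from general knowledge, with 1 base set by the reads.

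The rule for tags was tested on simulated data with the depths of the panicle libraries and 3379 tags. It recovered 94.8% of tags made 8-fold lower and 7.06% of those made 2-fold lower, and called 0.0658% of unchanged tags in the first setting. The simulated counts held counting error only. These rates therefore leave out differences between plants and library preparations and are not error rates of the rule in the real libraries.

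The alternatives tried were scaling to conserved miRNA reads, TMM factors and DESeq2 size factors over the miRNA families, other minima of reads and other fold limits, 21-nt reads alone, patterns starting 1 nt inside the read, other choosing libraries, no adaptor mismatch, adaptor-derived inserts kept, a filter for a quality of at least 10 at every insert base, removal of 5.8S rRNA reads, distinct sequences counted once, size classes and reads over tags without reads of the miRNA families, and other depths and seeds for duplexes. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. No model was fitted between groups: the plan fixed before the data were examined held no test with 1 library per group. An additive model of line and tissue over the 6 libraries was left out, since its spread would come from differences between lines in the tissue change.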

Results

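Small RNAs were sequenced from rice of 3 kinds: 93-11, a wild-type line of the subspecies indica; osdcl4-1, an indica line carrying a mutation in the gene for Dicer-like 4 (DCL4); and Nipponbare, a wild type of the subspecies japonica. The labels do not state whether osdcl4-1 was made in 93-11 itself, so differences between osdcl4-1 and 93-11 can include differences of background. DCL4 is the plant Dicer-like enzyme that cuts long double-stranded RNA into 21-nt small interfering RNAs. Each kind was sampled as seedlings and as young panicles of 4 cm, which gave 6 libraries with 1 library per group and no replicates. Differences between conditions were not tested, have no replicate check and carry no p-value. Changes were read by fixed rules of size together with 95% counting intervals, which cover counting error at most. With 1 library per group, they leave out differences between plants and library preparations. The reads also passed through 15 cycles of PCR without molecular identifiers, so copies of the same molecule can be counted repeatedly. The intervals may therefore be too narrow even for counting error. The series asks which small RNAs, and above all which phased siRNA clusters, depend on DCL4.

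The libraries held 3256147 reads for 93-11 seedlings, 4259422 for 93-11 panicles, 2640561 for osdcl4-1 seedlings, 4568991 for osdcl4-1 panicles, 2968766 for Nipponbare seedlings and 3390163 for Nipponbare panicles. After adaptor removal, 2863888, 4127057, 2314501, 4429513, 2324443 and 3149312 inserts of 18 to 28 nt were kept in the same order. A count of 0 allowed a level of up to 0.677 RPM (reads scaled to the size of the library) in the deepest library, osdcl4-1 panicles, and up to 1.30 RPM in the shallowest, osdcl4-1 seedlings. These libraries do not measure the DCL4 messenger RNA, so the genotype was not checked at its own gene. The miRNA lists, the rules of size, the scalings and the named families were fixed before the data were examined. The analysis of single sequences, called tags here, and of siRNA duplexes replaced phased loci after the libraries had been seen, since no genome was used.

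In panicles, 21-nt small RNAs made up a smaller share in osdcl4-1 than in either wild type. They were 6.90% of reads (exact 95% interval 6.88 to 6.92) in osdcl4-1, against 17.9% (17.9 to 17.9) in 93-11 and 33.2% (33.2 to 33.3) in Nipponbare. The 21-nt share of osdcl4-1 minus that of 93-11 was -10.998 percentage points (-11.042 to -10.954). The 24-nt class, which holds the siRNAs of repeats and of RNA-directed DNA methylation, made up 72.7% in osdcl4-1, 64.2% in 93-11 and 47.2% in Nipponbare panicles, and its difference between osdcl4-1 and 93-11 was 8.561 points (8.499 to 8.623). All lengths share one total, so a lower 21-nt share by itself raises the 24-nt share. The difference is therefore no measure of more 24-nt RNA in osdcl4-1. In seedlings the 21-nt share was 13.4% in osdcl4-1, 16.3% in 93-11 and 28.7% in Nipponbare, a difference of -2.86 points (-2.92 to -2.80) between the first pair. Outside the miRNA families the seedling order turned, with 21-nt reads at 8.66% of all reads in osdcl4-1 and 8.43% in 93-11, a difference of 0.235 points (0.187 to 0.284), while in panicles it was -10.836 points (-10.877 to -10.795). With each distinct sequence counted once, the differences were -3.12 (21 nt) and 3.05 points (24 nt) in panicles and -0.345 and -1.71 points in seedlings. The 24-nt share of seedlings was 42.1% in osdcl4-1, 44.3% in 93-11 and 36.3% in Nipponbare, and its difference of -2.18 points turned to 0.938 points when reads with a low-quality base were removed. The 2 wild types differed from each other in their 21-nt shares by more than osdcl4-1 differed from 93-11 in both tissues. Reads of 18, 19 and 25 to 28 nt, lengths outside the main Dicer products, made up 12.5% of reads in 93-11 seedlings, 19.8% in osdcl4-1 seedlings and 8.43% in Nipponbare seedlings, against 2.602%, 3.08% and 4.40% in the panicles of the same lines. Reads matching 5.8S ribosomal RNA were 1.46%, 1.81% and 1.03% in those seedlings and 0.0220%, 0.0777% and 0.332% in those panicles.

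**Figure D1:**
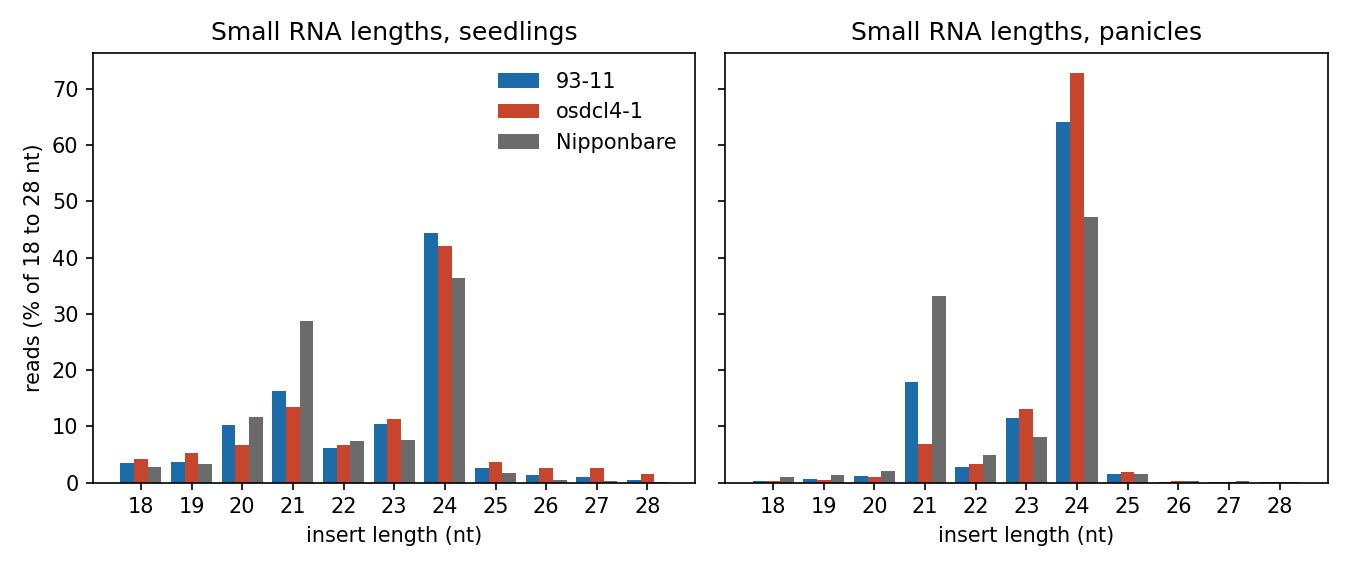
Share of reads at each insert length from 18 to 28 nt (horizontal axis, nt) in percent of all reads of those lengths (vertical axis), with 1 bar per library, for seedlings (left) and panicles (right). At 21 nt the panicle bars stand at 17.9% for 93-11, 6.90% for osdcl4-1 and 33.2% for Nipponbare.

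The first comparison asked which small RNAs of panicles were changed in osdcl4-1. Most 21-nt tags outside the miRNA families were lower in osdcl4-1 panicles than in 93-11 panicles, while 24-nt tags were mostly neither higher nor lower. Of 3335 measured 21-nt tags, 2578 (77.3%, exact interval 75.8 to 78.7) were at least 4-fold lower, 37 were at least 4-fold higher and 720 were neither. Their median log2 ratio was -2.55 (95% order-statistic interval -2.59 to -2.53), a 5.87-fold lower level. The intervals of this share and median take the tags as independent, which strands of the same duplex are not. They may be too narrow and do not measure the spread between plants. Of 2642 24-nt tags, 15 (0.568%, 0.318 to 0.935) were lower and 31 were higher, with a median of 0.01 (-0.02 to 0.03). These tags were chosen in Nipponbare panicles, a library outside the compared pair, by at least 10 reads there, and were measured where the pair held at least 20 reads together. Choosing the tags in 93-11 gave 4078 lower of 5200, and choosing them in osdcl4-1 gave 1298 lower of 2208.

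Among the other lengths, 1 of 128 measured 22-nt tags was lower and 34 were higher, with a median log2 ratio of 0.74 (0.59 to 1.12). Tags chosen in one library of the pair favour that library by construction: those chosen in 93-11 gave 7 lower and 16 higher of 216 with a median of 0.04, and those chosen in osdcl4-1 gave 1 lower and 143 higher of 362 with a median of 1.12. Of 57 tags of 20 nt, 7 were lower and 13 higher, and of 174 tags of 23 nt, 1 was lower and 10 were higher. Chosen in 93-11 and in osdcl4-1, the 20-nt tags gave 22 lower and 3 higher, and 0 and 14, and the 23-nt tags 17 and 3, and 1 and 23. With DESeq2 scaling the 24-nt tags split into 23 lower and 25 higher, with a shift of -0.18 in every log2 ratio, while scaling to conserved miRNAs shifted the ratios by 0.15. A 2-fold limit gave 157 lower and 141 higher 24-nt tags, and choosing these tags in 93-11 gave 217 lower and 10 higher of 13759, against 21 lower and 273 higher of 14862 when they were chosen in osdcl4-1.

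The 21-nt tags that were lower in osdcl4-1 began most often with C (33.9% of 2578 tags, 32.1 to 35.8), followed by A (23.7%), T (23.7%) and G (18.6%). Among the 720 tags that were neither, C also led at 37.5% (34.0 to 41.2), with T at 34.4% (31.0 to 38.0) and A at 14.3% (11.8 to 17.1). Tags whose exact duplex partner was also present in Nipponbare panicles were lower more often (1374 of 1657, 82.9%, 81.0 to 84.7) than tags without a partner there (1204 of 1678, 71.8%, 69.5 to 73.9). Their median log2 ratios lay closer, at -2.66 (-2.71 to -2.60) with a partner and -2.46 (-2.50 to -2.41) without. A tag with more reads passes the rule more easily, and read numbers were not matched between these sets.

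**Figure D2:**
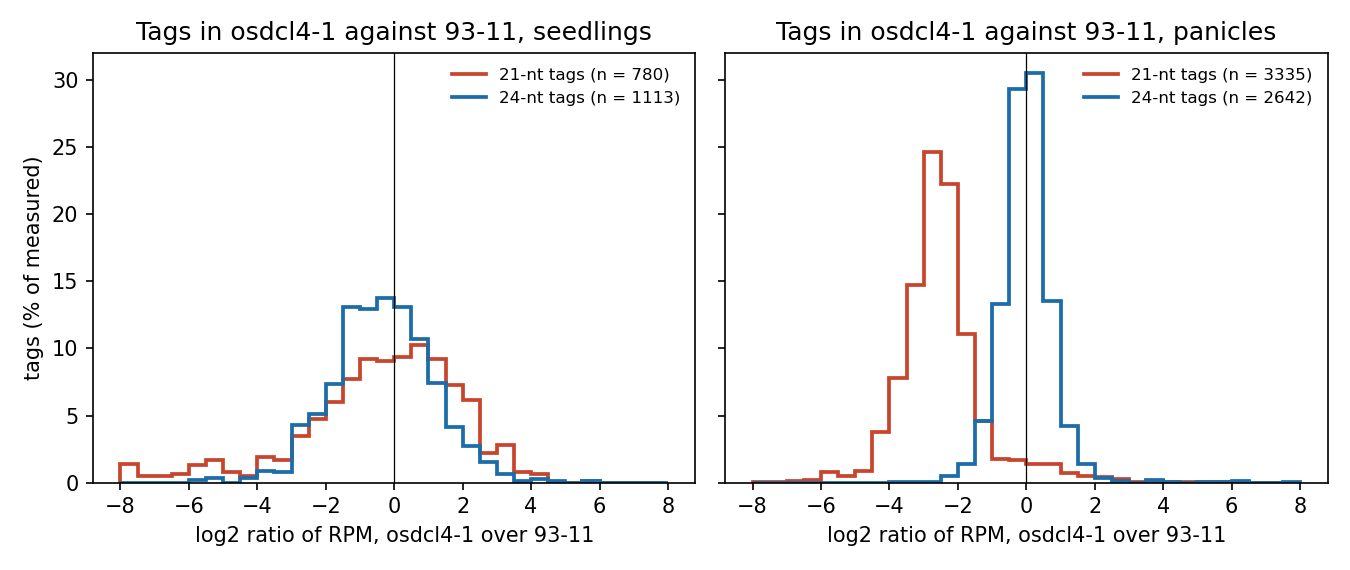
Log2 ratio of RPM in osdcl4-1 over 93-11 (horizontal axis) against the percent of measured tags in each interval (vertical axis), for 21-nt and 24-nt tags outside the miRNA families, in seedlings (left) and panicles (right). Tags beyond the axis are counted in the outermost intervals. In panicles the 21-nt tags lie around a median of -2.55 and the 24-nt tags around 0.01.

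Among the 10 most abundant 21-nt sequences of 93-11 panicles, 5 belonged to miRNA families and 5 did not. The most abundant, TCGCTTGGTGCAGATCGGGAC of miR168, which targets AGO1 transcripts, was at 13536 RPM in 93-11 and 10777 RPM in osdcl4-1 panicles, a ratio of 0.796 (0.786 to 0.806). AGAATCTTGATGATGCTGCAT of miR172 and TGAAGCTGCCAGCATGATCTA of miR167 had ratios of 0.949 and 0.888. The miR166 sequences TCGGACCAGGCTTCATTCCCC and TCGGACCAGGCTTCATTCCTC, directed against class III HD-ZIP transcription factors, were higher, with ratios of 2.24 (2.14 to 2.35) and 2.04 (1.94 to 2.15). Outside the families, GAGGACGAGAAATGTTGGCAA was at 2183 RPM in 93-11 and 578 RPM in osdcl4-1 panicles, a ratio of 0.265 (0.253 to 0.277), and at 2390 RPM in 93-11 seedlings against 63.1 RPM in osdcl4-1 seedlings. The remaining tags were almost confined to panicles: GTTGTCACGGAGTGTCGGCAT had a ratio of 0.154, TCTGGCAAAGAACAGAATGCA of 0.131, CTGTTCTTGTAGTGGGACGCA of 0.165 and GATGCACTGGAGAGAACACGG of 0.112, and none had more than 4 reads in any seedling library. No locus was assigned to the 5 tags outside the families, and they were not screened for miRNAs beyond the fixed lists.

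Duplexes with the 2-nt 3-prime overhangs that Dicer enzymes leave were counted by searching each library for the exact partner of each read. With libraries thinned to 2314501 inserts, 34.6% (34.5 to 34.8) of 21-nt reads outside the miRNA families had such a partner in 93-11 panicles and 37.5% in Nipponbare panicles. In osdcl4-1 panicles the share was 12.7% (12.5 to 12.9). The other overhangs from -6 to 8 nt, leaving out 1 and 3 nt, had a median share of 0.844% in 93-11, 1.25% in Nipponbare and 3.24% in osdcl4-1, and a largest share of 1.10%, 1.98% and 4.30%. Of 24-nt reads, 11.8% in 93-11, 9.53% in osdcl4-1 and 5.87% in Nipponbare panicles had a partner at 2 nt, against medians of 5.93%, 6.27% and 4.52% at other overhangs. The largest shares at those overhangs were 8.40%, 8.56% and 6.35%, the last above the share at 2 nt. For 22-nt reads the shares were 1.37% in 93-11, 6.40% in osdcl4-1 and 2.77% in Nipponbare panicles, against medians of 1.01%, 4.14% and 2.17% at other overhangs. Another overhang reached 1.49% in 93-11, 5.98% in osdcl4-1 and 3.03% in Nipponbare, and whether the 22-nt share at 2 nt stood above these in osdcl4-1 and Nipponbare changed with the random seed. Seedlings had lower shares of 21-nt reads with a partner, at 6.19% in 93-11, 2.21% in osdcl4-1 and 6.59% in Nipponbare, with medians of 2.15%, 1.91% and 3.69% at other overhangs. The largest shares there were 5.24%, 4.42% and 8.38%, so in osdcl4-1 and Nipponbare seedlings the share at 2 nt did not stand above all other overhangs. A partner is found more often in a larger set of reads, and with the same number of 21-nt reads per library the panicle shares were 27.6% in 93-11, 14.8% in osdcl4-1 and 25.3% in Nipponbare.

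**Figure D3:**
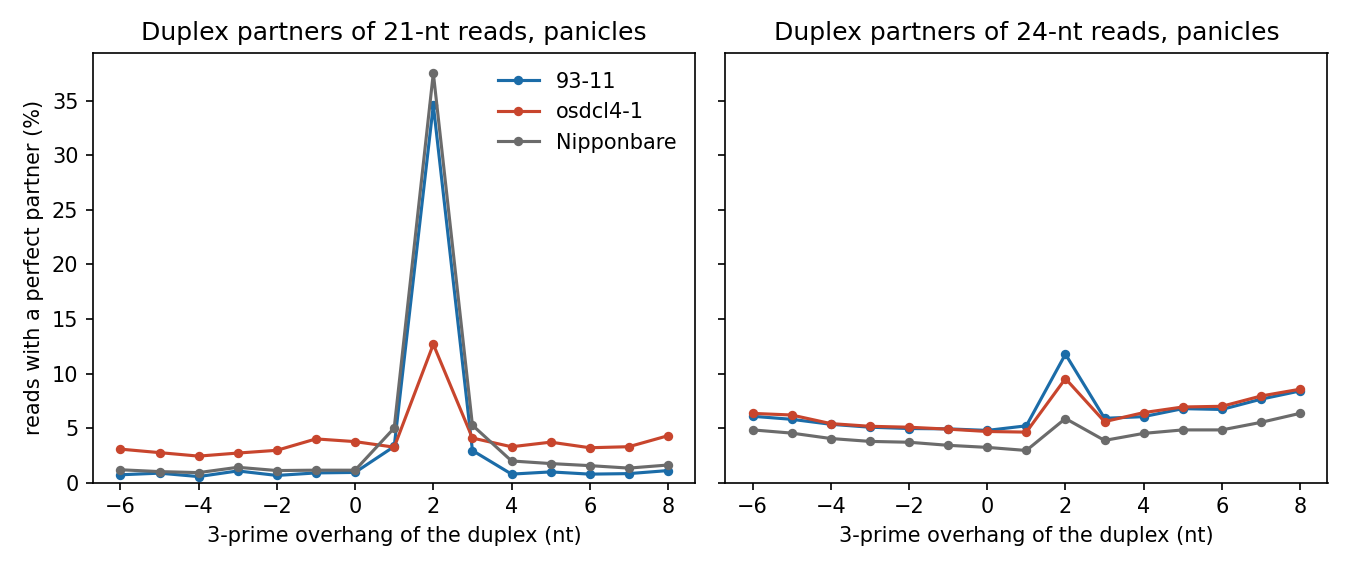
Percent of 21-nt (left) and 24-nt (right) reads outside the miRNA families whose exact partner strand was present in the same thinned panicle library (vertical axis), for each 3-prime overhang of the duplex from -6 to 8 nt (horizontal axis), with 1 line per library. At 2 nt the 21-nt lines reach 34.6% in 93-11, 37.5% in Nipponbare and 12.7% in osdcl4-1.

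All reads of 20 to 24 nt that shared a 16-nt stretch with the 3335 measured 21-nt tags were then counted on either strand, reads of the miRNA families included. In osdcl4-1 over 93-11 panicles the ratio was 0.342 (0.340 to 0.344) for 21-nt reads and 0.633 (0.611 to 0.656) for 20-nt reads, but 1.54 (1.497 to 1.581) for 22-nt, 1.25 (1.202 to 1.291) for 23-nt and 1.06 (1.05 to 1.08) for 24-nt reads. The 22-nt reads made up 7.14% of the reads over these tags in osdcl4-1, 2.01% in 93-11 and 3.52% in Nipponbare panicles, and the 21-nt reads 69.6%, 88.0% and 90.2%. The larger 22-nt share in osdcl4-1 than in 93-11 thus comes in part from the fall of 21-nt reads. Without reads of the miRNA families the ratio was 0.217 (0.215 to 0.219) for 21-nt, 1.72 (1.67 to 1.78) for 22-nt and 1.25 (1.203 to 1.293) for 23-nt reads, and the summed RPM of the tags themselves had a ratio of 0.204. Over the 2642 24-nt tags the 22-nt ratio was 1.22 (1.19 to 1.25). With family reads included, 22-nt reads over the 21-nt tags were at 3133 RPM in osdcl4-1, 2037 in 93-11 and 6157 in Nipponbare panicles, where the tags were chosen. In seedlings, again with family reads included, they were at 15994 RPM in osdcl4-1 and 17508 in 93-11. No seedling value without family reads is given here.

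tasiR-ARF, the trans-acting siRNA from TAS3 transcripts that targets auxin response factors and a known DCL4 product, was lower in osdcl4-1 panicles, at 9.71 RPM (43 reads) against 29.3 RPM (121 reads), a ratio of 0.331 (0.228 to 0.473) that stayed between 0.292 and 0.367 under all 4 scalings. Few miRNA families changed in panicles with RPM scaling. Of 26 families with at least 20 reads in the pair, 1 was at least 2-fold lower, 2 were higher and 23 were neither, with a median log2 ratio of 0.23. The lower one was tasiR-ARF itself, counted with the families. Higher were miR166 (2.15, 2.08 to 2.22; 1.89 with DESeq2 scaling) and miR390, the trigger of TAS3 cleavage (25 against 5 reads, 4.66, 1.75 to 15.6). None of the 6 monocot families passed in either direction with RPM scaling, while miR444 passed as higher when scaled to conserved miRNAs, at 2.11 (1.61 to 2.79). The phasiRNA triggers miR2118 (8 against 17 reads, 0.438, 0.164 to 1.07) and miR2275 (26 against 21 reads, 1.15, 0.624 to 2.16) had few reads, and with RPM scaling their intervals included a ratio of 1. miR162, which targets the DCL1 transcript, had a ratio of 1.19 and miR168 of 0.794. Scaling to conserved miRNAs gave 1 lower and 3 higher families, TMM 1 and 2, and DESeq2 scaling 2 and 1, with miR2118 joining the lower ones at 0.386.

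In seedlings, the second comparison, tasiR-ARF was again lower in osdcl4-1, while the 21-nt tags moved both ways. tasiR-ARF was at 5.62 RPM (13 reads) in osdcl4-1 and 43.3 RPM (124 reads) in 93-11, a ratio of 0.130 (0.0672 to 0.230), or 0.395 when scaled to conserved miRNAs. Of 780 measured 21-nt tags, 156 (20.0%, 17.2 to 22.98) were at least 4-fold lower and 104 (13.3%) higher, with a median log2 ratio of -0.08 (-0.26 to 0.10). Of 1113 24-nt tags, 144 were lower and 64 higher (median -0.29), and of 508 22-nt tags, 55 were lower and 90 higher. The directions of the 21-nt and 24-nt tags were not settled. The 22-nt split became 13 lower and 257 higher when scaled to conserved miRNAs, 63 and 71 with TMM and 47 and 110 with DESeq2 scaling. Without a minimum of reads it was close to even, at 105 and 107, with a median log2 ratio of -0.06 (-0.22 to 0.10). The 22-nt median with TMM was 0.21 (-0.06 to 0.36), so this direction was not settled either. The 21-nt split became 72 lower and 324 higher when scaled to conserved miRNAs, 171 and 72 with TMM and 127 and 135 with DESeq2 scaling. It was 41 and 439 with tags chosen in osdcl4-1 and 260 and 152 with tags chosen in 93-11, each choice favouring its own library. It was 80 and 90 with the base quality filter and 25 and 34 with a minimum of 200 reads. The 24-nt split became 20 lower and 344 higher when scaled to conserved miRNAs, 106 and 89 with DESeq2 scaling, 16 and 411 with tags chosen in osdcl4-1, 296 and 101 with tags chosen in 93-11, and 0 and 9 with a minimum of 200 reads.

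Among seedling miRNAs, 4 families were higher in osdcl4-1. These were miR408 (18.9-fold, 15.1 to 23.9), miR398 (16.1-fold, 9.16 to 30.8), miR528 (3.504-fold, 3.43 to 3.58) and miR397 (2.75-fold, 2.36 to 3.21), which target copper proteins, copper/zinc superoxide dismutases and laccases, and each stayed at least 2.39-fold higher under all 4 scalings. The osdcl4-1 seedlings also held more reads outside the main Dicer lengths (19.8% against 12.5%) and more 5.8S reads (1.81% against 1.46%) than the 93-11 seedlings. Of 29 families measured, 12 were lower, 4 were higher and 13 were neither, with a median log2 ratio of -0.47. The conserved list had 9 lower and 3 higher of 21, and the monocot list 2 lower and 1 higher of 7. Next to tasiR-ARF, the largest falls were those of miR167, which targets auxin response factors (0.133, 0.129 to 0.137), miR1432 (0.187), miR171 of the GRAS genes (0.191), miR529 (0.193) and miR156 (0.221), both directed against SPL transcription factors, miR172 of the AP2-like genes (0.201) and miR393 of the auxin receptors (8 against 41 reads, 0.241, 0.0978 to 0.522). miR168 was at 0.259 and miR162 at 0.448, and miR390 at 1.89 (1.63 to 2.20) did not reach 2-fold with RPM scaling. miR2118 had 1 read and miR2275 none in these libraries together.

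The seedling falls depended on the scaling, most of all on scaling to conserved miRNA reads. The families held 5.65% of reads in osdcl4-1 and 13.4% in 93-11 seedlings, and scaling to conserved miRNA reads shifted every log2 ratio by 1.61 (TMM -0.20, DESeq2 0.29), which gave 2 lower and 16 higher families, with DESeq2 at 11 and 6. Only miR167 (0.405) and tasiR-ARF stayed at least 2-fold lower under all 4 scalings, and miR162 (1.36) and miR827 (1.09) turned direction. Of the 366242 conserved miRNA reads in 93-11 seedlings, miR156 held 160897, miR168 123082 and miR167 49952. Those families were themselves lower in osdcl4-1 with RPM scaling, so scaling to conserved miRNA reads takes up part of their fall by construction. The growth of the osdcl4-1 seedlings is not stated in the labels, while both wild types were grown on MS medium with 16 h of light and 8 h of dark at 25 °C.

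**Figure D4:**
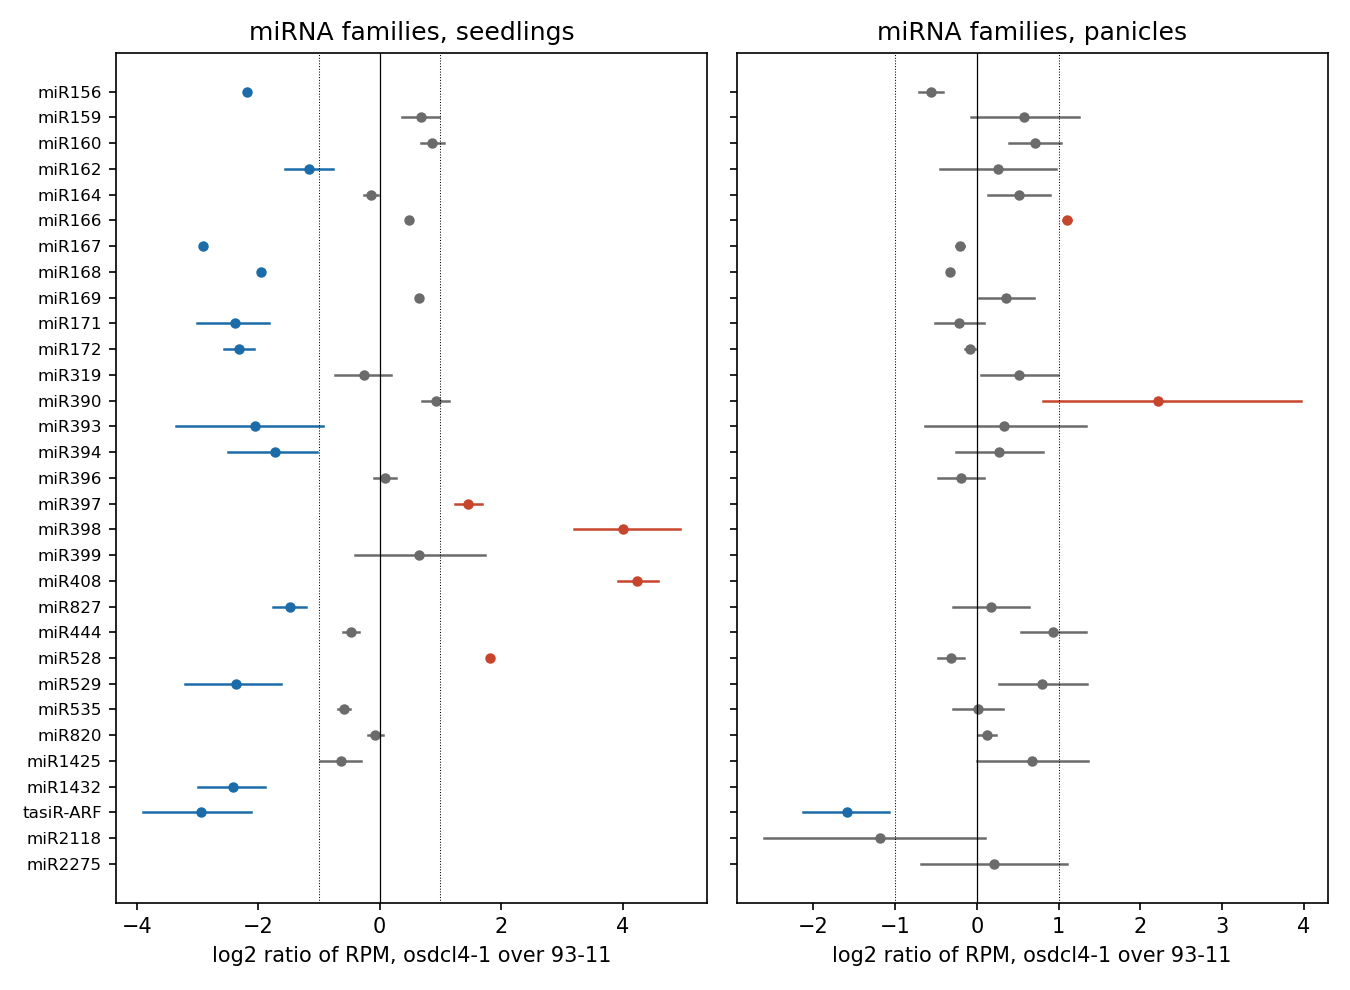
Log2 ratio of RPM in osdcl4-1 over 93-11 (horizontal axis) for each family with at least 20 reads in the pair (vertical axis), in seedlings (left) and panicles (right). Points are ratios, bars are 95% counting intervals, dotted lines mark 2-fold, blue marks lower, red higher and grey neither. In seedlings, 12 families are lower and 4 higher with RPM scaling, and 2 lower and 16 higher when scaled to conserved miRNAs, where miR162 and miR827 flip.

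The third comparison set panicles against seedlings of the same line. In both wild types most measured 21-nt tags outside the miRNA families were higher in panicles, but the lists held mostly panicle tags. Nipponbare panicles alone gave 11634 chosen 21-nt tags and Nipponbare seedlings alone 1615, against 13250 with both added together. For 93-11 these numbers were 8070, 1795 and 9983. The shares and medians of one line therefore partly reflect the make-up of its list. In 93-11, 2725 of 3524 measured tags (77.3%) were at least 4-fold higher and 607 lower, with a median log2 ratio of 5.40 (5.36 to 5.45). In Nipponbare, 3352 of 4132 (81.1%) were higher and 441 lower, with a median of 6.07 (6.00 to 6.13). In osdcl4-1, measured over tags chosen in Nipponbare as for 93-11, 551 of 1212 (45.5%) were higher and 492 lower, with a median of 0.20 (-0.43 to 1.10). The osdcl4-1 split was 421 lower and 585 higher (median 1.54) when scaled to conserved miRNAs, 295 and 655 (median 2.94) with TMM and 334 and 639 (median 2.59) with DESeq2 scaling, and it turned to 925 lower and 841 higher (median -0.81) for tags chosen in the compared libraries. It also turned with the base quality filter, to 339 lower and 231 higher of 660 with a median of -2.23 (-2.81 to -1.39), and with a minimum of 200 reads, to 77 lower and 12 higher of 100 with a median of -4.37 (-5.03 to -3.81). With RPM scaling the 22-nt tags went the other way, but their lists leaned toward seedlings, which favours lower calls in panicles. Nipponbare seedlings alone gave 1082 chosen 22-nt tags and Nipponbare panicles alone 549, and 93-11 gave 1071 and 278. Lower in panicles were 369 of 445 in 93-11, 293 of 486 in Nipponbare and 376 of 493 in osdcl4-1. Higher were 8, 22 and 25 in the same order. When scaled to conserved miRNAs these splits became 206 lower and 59 higher in 93-11, 319 and 52 in osdcl4-1, and turned to 100 and 119 in Nipponbare. They were 232 and 55, 208 and 83, and 188 and 61 with TMM, and 197 and 59, 235 and 71, and 187 and 61 with DESeq2 scaling, for 93-11, osdcl4-1 and Nipponbare. The 22-nt medians rose from -4.56 to -1.75, from -4.11 to -2.77 and from -2.68 to 0.11 when scaled to conserved miRNAs.

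The 24-nt lists leaned toward panicles, with 6175 tags from Nipponbare panicles alone and 3902 from its seedlings, and 16628 and 4058 from those of 93-11. Lower and higher in panicles were 366 and 677 of 3175 24-nt tags in 93-11 and 361 and 534 of 2413 in Nipponbare. In osdcl4-1 they were 352 and 1070 of 3082. Every other scaling widened those splits, to 102 lower and 2421 higher in 93-11, 67 and 1634 in Nipponbare and 224 and 1770 in osdcl4-1 when scaled to conserved miRNAs. They were 119 and 2246, 135 and 1054, and 113 and 2423 with TMM, and 90 and 2458, 131 and 1071, and 134 and 2312 with DESeq2 scaling, for the lines in that order.

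miRNA families were mostly lower in panicles with RPM scaling, where they held 1.89% of reads in 93-11 against 13.4% in seedlings, 1.71% against 5.65% in osdcl4-1 and 3.76% against 23.999% in Nipponbare. In 93-11, 23 of 28 measured families were lower and 2 were higher. The largest falls were those of miR156, which controls vegetative phase and panicle architecture through SPL genes (257-fold), miR169 of the NF-YA genes (145-fold), miR397 (3 against 246 reads, ratio 0.00846, 0.00173 to 0.0250), miR390 (85.0-fold), miR1432 (54.0-fold), miR408 (29.9-fold), miR444 of the MADS-box genes (22.5-fold) and miR528 (22.2-fold). These families were lower under all 4 scalings, as were miR164 and miR535, while 9 of the 23 turned direction under another scaling, among them miR168, at a ratio of 0.326 with RPM scaling. Few panicle reads lay behind miR390 (5 reads, ratio 0.0118, 0.00379 to 0.0278), miR1432 (6 reads, 0.0185, 0.00672 to 0.0409) and miR408 (4 reads, 0.0334, 0.00890 to 0.0889). miR172, which acts on AP2-like genes in flowering, was 3.12-fold higher (2.91 to 3.34), and miR2275 had 21 reads in panicles and 0 in seedlings, at least 4.86-fold higher against the limit that a count of 0 allows, with a counting interval from 3.61. tasiR-ARF had a ratio of 0.677, which lay above 1 under the 3 other scalings, miR162 of 0.107 and miR2118 17 reads against 1.

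In Nipponbare, 18 of 29 families were lower and 5 higher. miR156 was 112-fold, miR396 of the growth-regulating factors 14.7-fold and miR1432 14.5-fold lower, and these 3 passed under all 4 scalings. miR390 (8.21-fold) and miR444 (7.77-fold) kept their direction, whereas miR827 (6.87-fold), miR164 (6.50-fold) and miR168 (6.47-fold) turned to ratios of 1.01, 1.07 and 1.07 when scaled to conserved miRNAs, as 13 of the 18 did under some scaling. Higher were miR2118, the trigger of 21-nt phasiRNAs (20 reads against 0, at least 4.92-fold against that limit, interval from 3.64), miR2275, the trigger of 24-nt phasiRNAs (49 against 2 reads, 18.1-fold, 4.75 to 154), miR528 (7.75-fold), miR319 of the TCP genes (3.47-fold) and miR160 (2.13-fold). tasiR-ARF had a ratio of 0.315, which turned to 2.19 when scaled to conserved miRNAs, and miR162 of 0.472, which turned under the 3 other scalings.

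In osdcl4-1, 19 of 30 families were lower and 4 higher in panicles. miR408 (405-fold), miR397 (261-fold), miR169 (177-fold), miR528 (97.0-fold), miR156 (83.7-fold) and miR390 (34.5-fold) were lower under all 4 scalings, as were miR1432 (2 against 34 reads, ratio 0.0307, 0.00358 to 0.120) and miR398 (2 against 169 reads, ratio 0.00618, 0.000743 to 0.0227). The folds of miR408 and miR397 rested on 6 panicle reads (ratio 0.00247, 0.000905 to 0.00539) and 4 panicle reads (ratio 0.00383, 0.00104 to 0.00986). miR172 (14.7-fold), miR171 (3.24-fold) and miR529 (2.64-fold) were higher, and miR2275 had 26 reads against 0, at least 4.53-fold against that limit, with an interval from 3.43. miR168 had a ratio of 1.00, miR162 of 0.286 (above 1 with TMM and DESeq2 scaling), tasiR-ARF of 1.73 (0.912 to 3.503), and miR2118 8 reads against 0, too few for the rule. In all 3 lines the other scalings shifted the log2 ratios upward, by 2.52 to 2.87 in 93-11, 1.62 to 2.80 in Nipponbare and 1.35 to 2.75 in osdcl4-1. The splits then became 10 lower and 10 higher in 93-11, 3 and 15 in Nipponbare and 13 and 9 in osdcl4-1 when scaled to conserved miRNAs. With TMM they were 11 and 7, 8 and 10, and 9 and 13, and with DESeq2 scaling 10 and 11, 8 and 10, and 10 and 12.

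The last comparison set the wild types against each other, as a yardstick for osdcl4-1. The 21-nt tags of panicles, chosen in osdcl4-1 and thus favouring indica sequences, had 220 lower and 541 higher in 93-11 of 1973, with a median log2 ratio of 0.02 (-0.07 to 0.12), and those of seedlings 67 lower and 193 higher of 848 (median 0.44). The 24-nt tags had 146 lower and 3351 higher of 7066 in panicles (median 1.73) and 46 lower and 342 higher of 1263 in seedlings (median 0.65). The 22-nt tags had 50 lower and 30 higher of 174 in panicles (median -0.87) and 47 lower and 113 higher of 592 in seedlings (median 0.19). No 22-nt split under the other scalings is given here. Those scalings shifted every log2 ratio of the panicle pair upward by 0.889 to 1.868, more than the size of the 22-nt median. The direction of the 22-nt tags in panicles was thus not settled. With the other scalings the 21-nt split of panicles became 91 and 656 (conserved miRNAs), 41 and 941 (TMM) and 45 and 884 (DESeq2), and that of seedlings 31 and 300, 27 and 326, and 42 and 244. The 24-nt split became 57 and 4426, 25 and 5665, and 30 and 5490 in panicles, and 15 and 520, 14 and 543, and 25 and 423 in seedlings. With a minimum of 200 reads the 21-nt splits turned to 133 lower and 103 higher in panicles and 22 and 13 in seedlings, and the 24-nt split of seedlings to 7 and 2.

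Among miRNAs, 17 of 29 families were lower and 0 higher in 93-11 than in Nipponbare panicles. miR390 (62.1-fold), miR1432 (25.6-fold), miR164 of the NAC genes (23.2-fold), miR397 (3 against 46 reads, ratio 0.0498, 0.00990 to 0.155), miR528 (14.7-fold), miR535 (12.8-fold), miR444 (11.0-fold) and miR529 (7.35-fold) were lower under all 4 scalings. In 93-11 panicles miR390 had 5 reads (ratio 0.0161, 0.00518 to 0.0381) and miR1432 had 6 (ratio 0.0391, 0.0141 to 0.0878). miR2275 had 21 against 49 reads, a ratio of 0.327 that turned under TMM and DESeq2 scaling, as miR156 and miR166 did. miR162 had a ratio of 0.153, while the ratios of miR168 (0.688), tasiR-ARF (0.570) and miR2118 (17 against 20 reads, 0.649, 0.319 to 1.30) lay above 1 under the 3 other scalings. In seedlings 13 of 29 families were lower and 5 higher in 93-11. Higher under all 4 scalings were miR169 (39.6-fold, 35.02 to 44.91), miR528 (11.7-fold), miR397 (8.68-fold), miR319 (8.20-fold) and miR408 (6.74-fold). miR529 (7.75-fold), miR164 (7.02-fold), miR1432 (6.84-fold), miR390 (6.00-fold) and miR396 (5.35-fold) were lower under all 4 scalings, and miR444 (3.804-fold), tasiR-ARF (3.78-fold) and miR168 (3.07-fold) under some. miR162 had a ratio of 0.672, which lay above 1 when scaled to conserved miRNAs or with TMM. The other scalings shifted the log2 ratios by 0.89 to 1.87 in panicles and 0.50 to 0.97 in seedlings. In panicles the split became 13 lower and 1 higher (conserved miRNAs), 8 and 12 (TMM) and 9 and 9 (DESeq2), and in seedlings 7 and 8, 5 and 9, and 10 and 6.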

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

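Both measures given here were chosen only after the libraries had been seen, and no biological explanation was tested for them. Nipponbare seedlings held a signal in reads left out of the main comparisons: 1.70% of their inserts carried a stretch of an adaptor, against 1.41% in osdcl4-1 seedlings, 0.337% in 93-11 seedlings, 0.161% in Nipponbare panicles, 0.0586% in osdcl4-1 panicles and 0.0560% in 93-11 panicles. Inserts under 18 nt made up 14.5% of the reads of Nipponbare seedlings, against 6.40% in 93-11 seedlings, 5.76% in osdcl4-1 seedlings, 1.203% in Nipponbare panicles, 0.236% in osdcl4-1 panicles and 0.221% in 93-11 panicles. No miRNA family passed the rule of size as lower in osdcl4-1 in one tissue and higher in the other with RPM scaling, a comparison of calls that does not test the difference between tissues.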

How the results depend on the processing

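The scalings, the minima of reads and the fold limits of miRNA families, the 21-nt-only count, the distinct-sequence count and, for tissues, the tags chosen in the compared libraries were planned; all other alternatives were chosen after seeing the data. The scalings had been planned for phased loci and were carried over to tags. Each group held 1 library, so no replicate could be left out. A fit pairing the tissues by line over the 3 lines was not run. Not run for want of a genome were scaling to matched reads, phased loci with their stricter scores, single hits and wrong periods, the composition of loci chosen in 93-11, genome windows, and the removal of organelle and tRNA reads. The place of the miRNA lists among random lists was also not run, since 33 families are too few for it. The base quality filter left 28.1% of inserts in 93-11 panicles, 36.6% in osdcl4-1 panicles, 48.8% in Nipponbare panicles, 47.6% in 93-11 seedlings and 57.0% in osdcl4-1 seedlings. It was not applied to Nipponbare seedlings, so the tags chosen there were unfiltered. Depth limits tags with few reads: 3335 of 11634 chosen 21-nt tags had enough reads in the panicles of 93-11 and osdcl4-1.

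Over 73 results, 629 alternative values were computed: 311 stayed within 1.5 times the count or within the counting interval, 316 moved and 2 reversed. Lower and higher tags are counted there as separate results, so a split of tags can turn without a reversed value. The fall of 21-nt tags in osdcl4-1 panicles kept its direction under every alternative run, with more tags lower than higher. The tasiR-ARF ratio stayed below 0.5 in both tissues under every alternative run. Fewer tags pass a higher minimum, a quality filter or a higher fold limit by construction, and for all other moved values the cause was not tested. The 21-nt split of osdcl4-1 panicles against seedlings, 492 lower and 551 higher with a median log2 ratio of 0.20, turned under 3 alternatives. It became 339 lower and 231 higher (median -2.23) with the base quality filter, 77 and 12 (median -4.37) with a minimum of 200 reads, and 925 and 841 (median -0.81) with tags chosen in the compared libraries. The 21-nt split of osdcl4-1 against 93-11 seedlings, 156 lower and 104 higher, turned to 80 and 90 with the base quality filter, to 25 and 34 with a minimum of 200 reads, with scaling to conserved miRNAs, with DESeq2 scaling and with tags chosen in osdcl4-1. The 24-nt split of that pair, 144 and 64, turned under the same alternatives except the filter and DESeq2 scaling. A minimum of 200 reads also turned both splits of the wild-type seedlings and the 21-nt split of the wild-type panicles. The few 24-nt tags that differed between osdcl4-1 and 93-11 panicles, 15 lower and 31 higher, turned with a 2-fold limit and with tags chosen in 93-11. The 20-nt tags of that pair, 7 lower and 13 higher, turned to 20 and 19 without a minimum of reads and to 22 and 3 with tags chosen in 93-11, and the 23-nt tags, 1 and 10, to 17 and 3 with that choice. The 22-nt split of Nipponbare panicles against seedlings, 293 lower and 22 higher, turned to 100 and 119 when scaled to conserved miRNAs. Tags chosen in one library of a pair favour that library by construction, and the cause of the other turns was not tested. Patterns allowed to start 1 nt inside the read left the numbers of lower and higher families as they were in all 7 comparisons, although miR156 rose from 149573 to 270003 reads in Nipponbare seedlings. Values that moved follow, by setting.

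Scaling to conserved miRNA reads gave, for miRNA families, 2 lower and 16 higher in osdcl4-1 against 93-11 seedlings, 10 lower and 10 higher in 93-11 panicles against seedlings and 3 lower and 15 higher in Nipponbare panicles against seedlings. Also for miRNA families, it gave 1 higher in 93-11 against Nipponbare panicles, 7 lower and 8 higher in 93-11 against Nipponbare seedlings and 9 higher in osdcl4-1 panicles against seedlings. It gave 72 lower and 324 higher in osdcl4-1 against 93-11 seedlings, 294 lower in 93-11 panicles against seedlings and 155 lower in Nipponbare panicles against seedlings for 21-nt tags. It also gave 91 lower in 93-11 against Nipponbare panicles and 31 lower and 300 higher in 93-11 against Nipponbare seedlings. It gave 13 lower and 257 higher in osdcl4-1 against 93-11 seedlings, 206 lower and 59 higher in 93-11 panicles against seedlings and 100 lower and 119 higher in Nipponbare panicles against seedlings for 22-nt tags. It also gave 52 higher in osdcl4-1 panicles against seedlings. It gave 20 lower and 344 higher in osdcl4-1 against 93-11 seedlings, 102 lower and 2421 higher in 93-11 panicles against seedlings and 67 lower and 1634 higher in Nipponbare panicles against seedlings for 24-nt tags. It also gave 224 lower and 1770 higher in osdcl4-1 panicles against seedlings, 57 lower in 93-11 against Nipponbare panicles and 15 lower and 520 higher in 93-11 against Nipponbare seedlings. The tasiR-ARF ratio of seedlings became 0.395.

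TMM scaling gave, for miRNA families, 11 lower and 7 higher in 93-11 panicles against seedlings, 8 lower and 10 higher in Nipponbare panicles against seedlings and 8 lower and 12 higher in 93-11 against Nipponbare panicles. Also for miRNA families, it gave 5 lower and 9 higher in 93-11 against Nipponbare seedlings and 9 lower and 13 higher in osdcl4-1 panicles against seedlings. It gave 336 lower in 93-11 panicles against seedlings, 259 lower in Nipponbare panicles against seedlings and 295 lower in osdcl4-1 panicles against seedlings for 21-nt tags. It also gave 41 lower and 941 higher in 93-11 against Nipponbare panicles and 27 lower and 326 higher in 93-11 against Nipponbare seedlings. It gave 232 lower and 55 higher in 93-11 panicles against seedlings, 188 lower and 61 higher in Nipponbare panicles against seedlings and 208 lower and 83 higher in osdcl4-1 panicles against seedlings for 22-nt tags. It gave 119 lower and 2246 higher in 93-11 panicles against seedlings, 135 lower and 1054 higher in Nipponbare panicles against seedlings and 113 lower and 2423 higher in osdcl4-1 panicles against seedlings for 24-nt tags. It also gave 25 lower and 5665 higher in 93-11 against Nipponbare panicles and 14 lower and 543 higher in 93-11 against Nipponbare seedlings.

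DESeq2 scaling gave, for miRNA families, 2 lower and 1 higher in osdcl4-1 against 93-11 panicles, 10 lower and 11 higher in 93-11 panicles against seedlings and 8 lower and 10 higher in Nipponbare panicles against seedlings. Also for miRNA families, it gave 9 lower and 9 higher in 93-11 against Nipponbare panicles and 10 lower and 12 higher in osdcl4-1 panicles against seedlings. It gave 2 lower in osdcl4-1 against 93-11 panicles for 23-nt tags. It gave 23 lower in osdcl4-1 against 93-11 panicles, 90 lower and 2458 higher in 93-11 panicles against seedlings and 131 lower and 1071 higher in Nipponbare panicles against seedlings for 24-nt tags. It also gave 134 lower and 2312 higher in osdcl4-1 panicles against seedlings, 30 lower and 5490 higher in 93-11 against Nipponbare panicles and 25 lower in 93-11 against Nipponbare seedlings. It gave 276 lower in 93-11 panicles against seedlings, 254 lower in Nipponbare panicles against seedlings and 45 lower and 884 higher in 93-11 against Nipponbare panicles for 21-nt tags. It also gave 42 lower in 93-11 against Nipponbare seedlings. It gave 197 lower and 59 higher in 93-11 panicles against seedlings, 187 lower and 61 higher in Nipponbare panicles against seedlings and 235 lower and 71 higher in osdcl4-1 panicles against seedlings for 22-nt tags.

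A 4-fold limit gave, for miRNA families, 0 lower and 1 higher in osdcl4-1 against 93-11 panicles, 2 higher in osdcl4-1 against 93-11 seedlings and 1 higher in 93-11 panicles against seedlings. Also for miRNA families, it gave 11 lower and 3 higher in Nipponbare panicles against seedlings, 5 lower in 93-11 against Nipponbare seedlings and 2 higher in osdcl4-1 panicles against seedlings.

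A 2-fold limit gave, for 21-nt tags, 77 higher in osdcl4-1 against 93-11 panicles, 243 lower and 222 higher in osdcl4-1 against 93-11 seedlings and 535 lower in 93-11 against Nipponbare panicles. It also gave 159 lower and 296 higher in 93-11 against Nipponbare seedlings. It gave 4 lower and 53 higher in osdcl4-1 against 93-11 panicles, 95 lower and 173 higher in osdcl4-1 against 93-11 seedlings and 14 higher in 93-11 panicles against seedlings for 22-nt tags. It also gave 35 higher in Nipponbare panicles against seedlings and 39 higher in osdcl4-1 panicles against seedlings. It gave 10 lower and 24 higher in osdcl4-1 against 93-11 panicles for 23-nt tags. It gave 157 lower and 141 higher in osdcl4-1 against 93-11 panicles, 323 lower and 185 higher in osdcl4-1 against 93-11 seedlings and 594 lower and 1019 higher in 93-11 panicles against seedlings for 24-nt tags. It also gave 645 lower in Nipponbare panicles against seedlings, 545 lower in osdcl4-1 panicles against seedlings and 412 lower in 93-11 against Nipponbare panicles. It also gave 152 lower in 93-11 against Nipponbare seedlings.

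Dropping the minimum of reads gave, for miRNA families, 4 higher in 93-11 panicles against seedlings. It gave 20 lower in osdcl4-1 against 93-11 panicles for 20-nt tags. It gave 3982 lower and 65 higher in osdcl4-1 against 93-11 panicles, 246 lower in osdcl4-1 against 93-11 seedlings and 1058 lower and 4885 higher in 93-11 panicles against seedlings for 21-nt tags. It also gave 797 lower and 1377 higher in osdcl4-1 panicles against seedlings and 372 higher in 93-11 against Nipponbare seedlings. It gave 7 lower in osdcl4-1 against 93-11 panicles, 105 lower in osdcl4-1 against 93-11 seedlings and 710 lower and 16 higher in 93-11 panicles against seedlings for 22-nt tags. It also gave 465 lower and 46 higher in Nipponbare panicles against seedlings and 593 lower in osdcl4-1 panicles against seedlings. It gave 17 higher in osdcl4-1 against 93-11 panicles for 23-nt tags. It gave 38 lower and 96 higher in osdcl4-1 against 93-11 panicles, 315 lower in osdcl4-1 against 93-11 seedlings and 957 lower and 1066 higher in 93-11 panicles against seedlings for 24-nt tags. It also gave 777 lower and 1780 higher in Nipponbare panicles against seedlings, 730 lower and 1668 higher in osdcl4-1 panicles against seedlings and 254 lower and 8815 higher in 93-11 against Nipponbare panicles. It also gave 79 lower and 784 higher in 93-11 against Nipponbare seedlings.

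A minimum of 200 reads gave, for miRNA families, 0 lower and 1 higher in osdcl4-1 against 93-11 panicles, 1 higher in 93-11 panicles against seedlings and 2 higher in Nipponbare panicles against seedlings. Also for miRNA families, it gave 11 lower in 93-11 against Nipponbare panicles, 3 higher in 93-11 against Nipponbare seedlings and 2 higher in osdcl4-1 panicles against seedlings. For 20-nt tags it gave 0 lower and 1 higher in osdcl4-1 against 93-11 panicles. It gave 286 lower and 1 higher in osdcl4-1 against 93-11 panicles, 25 lower and 34 higher in osdcl4-1 against 93-11 seedlings and 53 lower and 249 higher in 93-11 panicles against seedlings for 21-nt tags. It also gave 58 lower and 430 higher in Nipponbare panicles against seedlings, 77 lower and 12 higher in osdcl4-1 panicles against seedlings and 133 lower and 103 higher in 93-11 against Nipponbare panicles. It also gave 22 lower and 13 higher in 93-11 against Nipponbare seedlings. For 22-nt tags it gave 0 lower and 2 higher in osdcl4-1 against 93-11 panicles, 2 lower and 23 higher in osdcl4-1 against 93-11 seedlings and 16 lower and 0 higher in 93-11 panicles against seedlings. It also gave 22 lower and 0 higher in Nipponbare panicles against seedlings and 41 lower and 1 higher in osdcl4-1 panicles against seedlings. For 23-nt tags it gave 0 lower and 0 higher in osdcl4-1 against 93-11 panicles. For 24-nt tags it gave 0 lower and 3 higher in osdcl4-1 against 93-11 panicles, 0 lower and 9 higher in osdcl4-1 against 93-11 seedlings and 14 lower and 64 higher in 93-11 panicles against seedlings. It also gave 15 lower and 27 higher in Nipponbare panicles against seedlings, 33 lower and 69 higher in osdcl4-1 panicles against seedlings and 8 lower and 143 higher in 93-11 against Nipponbare panicles. It also gave 7 lower and 2 higher in 93-11 against Nipponbare seedlings.

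Choosing tags in 93-11 gave, for 20-nt tags, 22 lower and 3 higher in osdcl4-1 against 93-11 panicles. It gave 4078 lower and 12 higher in osdcl4-1 against 93-11 panicles and 260 lower in osdcl4-1 against 93-11 seedlings for 21-nt tags. It gave 7 lower and 16 higher in osdcl4-1 against 93-11 panicles and 87 lower in osdcl4-1 against 93-11 seedlings for 22-nt tags. It gave 17 lower and 3 higher in osdcl4-1 against 93-11 panicles for 23-nt tags. It gave 217 lower and 10 higher in osdcl4-1 against 93-11 panicles and 296 lower and 101 higher in osdcl4-1 against 93-11 seedlings for 24-nt tags.

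Choosing tags in osdcl4-1 gave, for 20-nt tags, 0 lower in osdcl4-1 against 93-11 panicles. It gave 1298 lower and 153 higher in osdcl4-1 against 93-11 panicles and 41 lower and 439 higher in osdcl4-1 against 93-11 seedlings for 21-nt tags. It gave 143 higher in osdcl4-1 against 93-11 panicles and 11 lower and 390 higher in osdcl4-1 against 93-11 seedlings for 22-nt tags. It gave 23 higher in osdcl4-1 against 93-11 panicles for 23-nt tags. It gave 273 higher in osdcl4-1 against 93-11 panicles and 16 lower and 411 higher in osdcl4-1 against 93-11 seedlings for 24-nt tags.

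Choosing tags in the compared libraries gave, for 21-nt tags, 4224 higher in 93-11 panicles against seedlings, 684 lower and 6518 higher in Nipponbare panicles against seedlings and 925 lower and 841 higher in osdcl4-1 panicles against seedlings. It gave 29 higher in 93-11 panicles against seedlings, 54 higher in Nipponbare panicles against seedlings and 733 lower and 113 higher in osdcl4-1 panicles against seedlings for 22-nt tags. It gave 3441 higher in 93-11 panicles against seedlings, 656 lower and 1041 higher in Nipponbare panicles against seedlings and 749 lower and 4441 higher in osdcl4-1 panicles against seedlings for 24-nt tags.

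The base quality filter gave, for miRNA families, 1 higher in 93-11 panicles against seedlings. For 20-nt tags it gave 0 lower and 2 higher in osdcl4-1 against 93-11 panicles. It gave 1310 lower and 15 higher in osdcl4-1 against 93-11 panicles, 80 lower and 90 higher in osdcl4-1 against 93-11 seedlings and 306 lower and 1300 higher in 93-11 panicles against seedlings for 21-nt tags. It also gave 339 lower and 231 higher in osdcl4-1 panicles against seedlings and 74 lower and 248 higher in 93-11 against Nipponbare panicles. For 22-nt tags it gave 0 lower and 17 higher in osdcl4-1 against 93-11 panicles, 28 lower in osdcl4-1 against 93-11 seedlings and 166 lower and 1 higher in 93-11 panicles against seedlings. It also gave 240 lower and 11 higher in osdcl4-1 panicles against seedlings. For 23-nt tags it gave 0 lower and 3 higher in osdcl4-1 against 93-11 panicles. It gave 1 lower and 11 higher in osdcl4-1 against 93-11 panicles, 67 lower in osdcl4-1 against 93-11 seedlings and 141 lower and 186 higher in 93-11 panicles against seedlings for 24-nt tags. It also gave 196 lower and 379 higher in osdcl4-1 panicles against seedlings and 47 lower and 581 higher in 93-11 against Nipponbare panicles. The size differences became -14.4 (21 nt) and 11.3 (24 nt) points in panicles and -3.18 (21 nt) points in seedlings, while the 24-nt difference of seedlings reversed from -2.18 to 0.938 points.

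An adaptor match without mismatch gave, for miRNA families, 1 higher in 93-11 panicles against seedlings. It gave 3 lower in osdcl4-1 against 93-11 panicles for 20-nt tags. It gave 34 higher in osdcl4-1 against 93-11 seedlings for 24-nt tags. Requiring an adaptor match without mismatch gave size differences of -11.3 (21 nt) and 8.85 (24 nt) points in panicles, and -2.29 and -2.98 points in seedlings.

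Keeping adaptor-derived inserts gave a 24-nt difference of -2.36 points in seedlings.

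Leaving out 5.8S rRNA reads gave -2.01 points there.

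Counting each distinct sequence once gave differences between osdcl4-1 and 93-11 of -3.12 (21 nt) and 3.05 (24 nt) points in panicles, and -0.345 and -1.71 points in seedlings.

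At full depth the duplex shares of panicles were 39.7% (93-11), 15.8% (osdcl4-1) and 40.4% (Nipponbare) of 21-nt reads, and 14.5%, 12.7% and 6.75% of 24-nt reads.

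Without reads of the miRNA families, the ratios of osdcl4-1 over 93-11 panicles for reads over 21-nt tags became 0.217 (21 nt) and 1.72 (22 nt). The 21-nt size difference became -10.836 points in panicles and reversed from -2.86 to 0.235 points in seedlings, where the families held 5.65% of reads in osdcl4-1 and 13.4% in 93-11.

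Another random seed gave 12.3% of 21-nt reads in osdcl4-1 and 11.7% of 24-nt reads in 93-11.

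The same number of reads per length gave 27.6%, 14.8% and 25.3% of 21-nt reads, and 9.61%, 6.81% and 5.22% of 24-nt reads, in that order.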

Other observations

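The tests of the 4 families higher in osdcl4-1 seedlings, whose grouping was made from their values, and of 22-nt reads were chosen only after the result was seen, while the tests on the fall of 21-nt tags were written before it. Sequences seen in a single library, miRNA families included, differed in number and length between the libraries. With at least 20 reads in 1 library and 0 in the 5 others, Nipponbare panicles held 1875 such sequences, of which 1595 (85.1%) had 21 nt, 14 had 22 nt and 253 had 24 nt. 93-11 panicles held 49, of which 42 had 21 nt and none had 22 nt. In osdcl4-1 panicles there were 138, of which 56 had 21 nt, 45 (32.6%) had 22 nt and 35 had 24 nt. The seedlings held 81 in Nipponbare, 54 in 93-11 and 24 in osdcl4-1. Nipponbare is the only japonica line here, so its sequence differences from the 2 indica lines enter this count.

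The first base of small RNAs outside the miRNA families differed with length. Of 24-nt reads, 56.4% began with A in Nipponbare seedlings, 47.8% in Nipponbare panicles, 47.3% in 93-11 seedlings, 44.8% in osdcl4-1 seedlings, 38.8% in 93-11 panicles and 38.8% in osdcl4-1 panicles. Of 21-nt reads, 34.3% began with C in Nipponbare panicles, 28.9% in 93-11 panicles and 26.6% in osdcl4-1 panicles, and in seedlings 14.1% in Nipponbare, 22.2% in 93-11 and 37.7% in osdcl4-1. Of 20-nt reads, 58.1% began with G in Nipponbare seedlings, 38.9% in 93-11 seedlings and 36.5% in osdcl4-1 seedlings, against 23.2%, 21.8% and 21.6% in the panicles of the same lines.

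Loss of DCL4 may underlie the fall of 21-nt tags in osdcl4-1 panicles, a hypothesis on 1 library per group. The median log2 ratio of the tags minus that of the miRNA families was -2.78, which argues against the scaling of libraries. Only 0.568% of 24-nt tags chosen the same way were lower, which argues against sequence differences between the osdcl4-1 background and 93-11. With the base quality filter the median was -2.60, which argues against base quality. Differences between the field plants or library preparations other than the mutation stay open, because they go with the genotype.

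The rise of miR397, miR398, miR408 and miR528 in osdcl4-1 seedlings was at least 2.39-fold (2.05 to 2.79) over these families and all 4 scalings. These families were picked because they passed 2-fold with RPM scaling. Among the other scalings only TMM lowered their log2 ratios, by a shift of -0.20, against 1.61 and 0.29 for the others. The test could thus hardly come out otherwise and does not decide on scaling as the cause. Differences between seedling batches unrelated to the mutation stay open: 3 of the 4 families, all but miR398, also differed at least 2-fold between the wild-type seedlings, but so did 18 of all 29 measured families, and that pair differs in subspecies. The growth of the osdcl4-1 seedlings is not stated in the labels, so growth conditions stay open beside the mutation. So does the quality of the RNA, which was not tested for these families, since reads outside 20 to 24 nt were 19.8% in osdcl4-1 and 12.5% in 93-11 seedlings.

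Another Dicer-like enzyme may process part of the DCL4 substrates into 22-nt RNAs in osdcl4-1 panicles. The 22-nt reads over 21-nt tags had a ratio of 1.54 to 93-11 (1.72 without miRNA family reads), which argues against 21-nt RNAs with an added or misread base, since 21-nt reads there had a ratio of 0.342 (0.217). With family reads included, the ratio over 21-nt tags was 0.633 for 20-nt and 1.25 for 23-nt reads. These ratios do not decide on RNA breakdown, since 20-nt reads fell together with 21-nt reads and 23-nt reads rose. Reads of 5.8S rRNA were 0.0777% in osdcl4-1 and 0.0220% in 93-11 panicles, so RNA breakdown stays open. Over 24-nt tags the 22-nt ratio was 1.22, so part of the 22-nt rise was not specific to 21-nt tags. With family reads included, the 22-nt level over 21-nt tags in osdcl4-1 panicles (3133 RPM) lay between those of 93-11 (2037) and Nipponbare panicles (6157). In seedlings, also with family reads included, it was lower in osdcl4-1 (15994 RPM) than in 93-11 (17508). No seedling value without family reads is given, so this order may come from the families. All 22-nt reads outside the families were 6.61% of reads in osdcl4-1 and 5.10% in 93-11 seedlings. The hypothesis stays open and no test here names the enzyme. Duplexes were sought among all 145796 22-nt reads of osdcl4-1 panicles outside the families, of which 12341 overlapped the 21-nt tags. The search therefore cannot show the overhang of the overlapping reads. The whole pool showed no clear Dicer overhang: 6.40% had a partner at 2 nt against at most 5.98% at another overhang. The values were 5.76% against 6.15% with another random seed and 7.67% against 7.94% at full depth.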
